A study of Mus musculus with 4 samples.

How the data were processed

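Single-cell libraries were made from mouse bone marrow cells sorted as CD34- KSL, with 1 library per group: young mice with PBS, young mice with EGF, aged mice with PBS and aged mice with EGF. Per the labels, EGF was given at 1 µg/g in 200 µL under the skin daily for 3 days. The control is called saline in some labels and PBS in others. The number of mice behind each library is not given in the sources used here. Per the submitters' processing notes, the authors made the UMI count matrices with Cell Ranger 7.0.1 (the file headers give 7.0.0) against mm10 and later used R 4.2.2, Seurat 4.2.1, Scran normalization and DESeq2 within Partek Flow. Per the labels the kit version is given both as V2 and as v3.1. Whether intronic reads were counted is not given in the sources used here. The deposited matrices hold raw UMI counts of 32285 genes, and no value in them was normalised, per the file headers and the values. The steps below were computed from these counts.

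Of 5389 barcodes, 5147 had at least 1000 genes and at most 10% mitochondrial UMIs. The doublet caller Scrublet, with an expected rate of 0.05, marked 14 cells (0.272%), which were left out. That share is far below the expected rate, and the number of doublets that remain was not measured. Plasma-like and T or NK-like clusters were left out as well, which kept 5028 cells. Clusters came from 2000 variable genes without cell cycle genes, 10 principal components, 20 neighbours and the Leiden method at resolution 0.5 (scanpy 1.11.5, leidenalg 0.10.2), which gave 12 clusters. A cluster was called after a cell type only from markers fixed before the data were examined, with at least 3 of them raised. Coordinates came from the GENCODE annotation of GRCm38, to which 32235 genes matched by identifier.

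Raw counts were summed over the kept cells of each library and scaled to counts per library total (CPM). A gene entered a contrast with at least 100 UMIs and 20 CPM in the higher library, and a list member with at least 20 UMIs. Each ratio has an exact conditional Clopper-Pearson interval of 95%, and a log2 ratio uses a pseudocount of 0.5 UMI. A count of 0 is given with a floor of 3 UMIs per library. Contrasts between a pair of libraries have no test. Age and EGF effects were tested with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood F test with TMM factors, the default expression filter and Benjamini-Hochberg adjustment, in a model with 3 coefficients and 1 residual degree of freedom. A call there concerns the average change over both levels of the other factor, against a spread that is moderated across genes, so the change of a called gene can differ between those levels. edgeR gives no standard error of a fold change, so none is printed. DESeq2 1.42.0 was fitted with the same design as an alternative.

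The 33 gene lists covered HSC ageing, stem cell identity, multipotent and lymphoid, granulocyte and monocyte, megakaryocyte and erythroid priming, ERBB and ERK signalling, immediate early genes, DNA repair, apoptosis and p53, cell cycle, interferon, NF-kB, metabolism, translation, stress responses, antigen presentation, autophagy and X inactivation. Each median was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Lists of histone and ribosomal RNA locus genes were added after the data were seen. The naming rule took the 10 highest and 10 lowest ratios of 3 contrasts and of EGF at both ages (predicted gene models left out, and the ratio holding without the 1% of cells with the most UMIs of the gene), the 10 genes of lowest p per direction of the additive model, up to 4 members per list, and the detected ERBB genes. The values of a few single members of the apoptosis and translation lists are not reported. For phases, each cell was thinned to 6000 UMIs, the largest multiple of 1000 that at least 90% of the kept cells of every library reach, and 265 shallower cells were left out. Within 0.05 of the phase boundary lay 337, 173, 401 and 170 cells of young PBS, young EGF, aged PBS and aged EGF. For the ratios that share a library, 100 simulations without effect were drawn.

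The ratio step was tested on simulated data with 200 changed genes per contrast. These data held counting error only, so the test does not cover variation between libraries. It recovered 100% of 2-fold and 100% of 4-fold changes, and the interval covered the true ratio for 95.3%, 95.1%, 95.3% and 95.2% of genes (age without EGF, age with EGF, EGF in young, EGF in aged; 6880, 6849, 6888 and 6878 genes). For the EGF effect the additive step recovered 46.3% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes among 15130 genes, with 4 false calls. Its simulated libraries varied independently per gene, with a coefficient of variation set at 0.1. That spread was not measured in the real libraries, so recovery and false calls hold for this setting only. Alternatives covered library scaling, cell weights, depth, cell filters, cell classes, gene filters, the ratio threshold and the design and tool of the additive model. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.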

Results

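Messenger RNA was counted in single bone marrow cells of mice, sorted as CD34- KSL cells. These cells carry c-Kit and Sca-1 and lack both lineage markers and CD34, a gate that enriches long-term haematopoietic stem cells (HSCs). The mice were young or aged and had been injected under the skin on 3 days with epidermal growth factor (EGF), the ligand of the receptor tyrosine kinase EGFR, at a dose of 1 µg/g, or with phosphate-buffered saline (PBS). The title of the series asks whether EGF moves aged HSCs towards a young state. The 4 libraries, 1 per group, held 1405 barcodes and 19972209 UMIs (young PBS), 940 barcodes and 23359278 UMIs (young EGF), 2076 barcodes and 23954617 UMIs (aged PBS), and 968 barcodes and 21054926 UMIs (aged EGF). After filters, 1313, 888, 1935 and 892 cells were kept, in the same order. Depth per cell differed with treatment: the median kept cell held 10923 UMIs in young PBS and 9987 in aged PBS, against 19390 in young EGF and 18870 in aged EGF. With 1 library per group, a difference between any pair of libraries had no replicate check. Ratios are those of summed UMIs scaled to library totals (CPM), and the intervals in brackets are exact 95% intervals that cover counting error only. The words rose and fell are kept for genes that passed an additive model of age and EGF over the 4 libraries. Genes were named by a rule set before the data were examined, except that members of short lists named as having risen or fallen, and Gm42418, were chosen after their values were seen.

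The receptor for EGF was at the edge of detection. Egfr had 0 UMIs in young PBS, 0 in young EGF, 5 in aged PBS and 2 in aged EGF, where a count of 0 allows up to 0.156 CPM in young PBS and 0.132 CPM in young EGF. Erbb2, the usual partner of EGFR, had 0 UMIs in all 4 libraries. Erbb3 had 54, 42, 28 and 23 UMIs and Erbb4 had 2, 2, 8 and 17, in the order young PBS, young EGF, aged PBS and aged EGF. Among the ligands, Hbegf stood at 10.2, 9.82, 11.7 and 11.3 CPM, Egf itself at 2.18, 4.45, 2.30 and 3.25 CPM, Nrg1 at 0.987, 0.969, 1.65 and 2.15 CPM, and Tgfa at 0.468, 0.396, 0.913 and 0.849 CPM. Btc had 77, 81, 110 and 76 UMIs and Areg had 4, 3, 3 and 11, while Ereg had 0 in all 4 libraries. The feedback inhibitors Errfi1 and Lrig1 had 346 and 83 UMIs over the 4 libraries. Adam17, the protease that sheds ERBB ligands, was the most abundant of the group at 34.4, 51.6, 27.4 and 39.3 CPM. Of the 9 members that entered the additive edgeR model, only Adam17 passed for EGF (log2 fold change 0.32, adjusted p = 0.044), and with DESeq2 its adjusted p was 0.24. Xist, transcribed from the inactive X chromosome, was present in all 4 libraries at 1377, 1628, 1151 and 1448 CPM, and it did not pass the test for age or EGF.

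The first comparison asked how aged CD34- KSL cells differed from young ones without EGF. Aged cells carried a set of transcripts that were far scarcer in young cells. Kcnb2, a voltage-gated potassium channel subunit (ENSMUSG00000092083, chromosome 1, 15287254 to 15723750, build GRCm38), stood at 0.312 CPM in young and 72.4 CPM in aged PBS cells, a ratio of 232 (106 to 634). The nuclear receptor Rorb was 65.0-fold higher (40.5 to 112), the scramblase family member Plscr2 46.0-fold (28.6 to 79.3), the muscarinic receptor Chrm3 38.3-fold (31.0 to 47.8) and the stress-responsive regulator Nupr1 25.2-fold (20.2 to 31.7; ENSMUSG00000030717, chromosome 7, 126623249 to 126630861). The Hippo pathway coactivator Wwtr1 was 21.3-fold higher (14.2 to 33.5), and the bone morphogenetic protein receptor Bmpr1a was also among the 10 highest (16.4-fold to 40.2-fold). Also high were Eya4 at 19.5-fold (13.5 to 29.1), the oxysterol receptor Gpr183 18.3-fold (12.7 to 27.3) and Naaladl2 14.9-fold (10.4 to 21.9). Among the genes lowest in aged cells were B-lymphoid and erythroid genes. Ebf1, a transcription factor of B cell commitment (ENSMUSG00000057098, chromosome 11, 44617317 to 45008091), was 47.3-fold lower (35.1 to 65.4), the B cell receptor chain Cd79a 28.8-fold and the surrogate light chain Vpreb1 9.93-fold (7.70 to 13.0). Vpreb3 and Igll1 had 0 UMIs in both aged libraries. Against a floor of 3 UMIs per library they were at least 147-fold and 106-fold lower in aged PBS than in young PBS cells. These B-lymphoid genes were concentrated in a cluster of 27 pro-B-like cells, set apart only by the clustering on 30 principal components, which held 21 young PBS and 0 aged PBS cells. Ebf1 stood there at 1031 CPM against 5.54 CPM in the rest, and Vpreb3 at 594 CPM against 0.266 CPM. Without erythroid-like and pro-B-like cells, the log2 ratio of Ebf1 moved from -5.55 to -2.08 and that of Vpreb1 from -3.30 to -0.24. The carbonic anhydrase Car1 was 5.65-fold lower (5.33 to 5.98), the erythroid transcription factor Klf1 5.50-fold (4.49 to 6.78) and the erythroid membrane protein Ermap 4.92-fold (4.11 to 5.93). Hmga2, a chromatin protein abundant in fetal and young HSCs, was 3.48-fold lower (3.13 to 3.86). Bfsp2, Arpp21 and Slc25a21 were 5.57-fold, 3.41-fold and 3.17-fold lower. The log2 ratio of Slc25a21 turned from -1.66 to 1.12 when erythroid-like and pro-B-like cells were left out.

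Of 6721 genes compared, 198 were at least 1.5-fold higher and 227 at least 1.5-fold lower in aged PBS cells. Genes higher made up 46.6% of these calls with CPM and 55.4% with TMM factors. After centring on the all-gene median, 277 were higher and 130 lower. In the additive model with EGF as a second term, which leaves 1 residual degree of freedom and takes its spread from the departure from additivity, moderated across genes, 1109 genes rose and 945 fell with age among 14911 tested (edgeR, adjusted p under 0.05). DESeq2 called 431 and 255, of which 408 and 253 were also called by edgeR. Without the EGF term edgeR called 152 and 27. The genes of lowest edgeR p that rose were Kcnb2 (log2 fold change 8.10, adjusted p = 1.7e-22), Rorb, Chrm3, Plscr2, Nupr1 (4.35, adjusted p = 3.6e-19), Eya4, Wwtr1, Aldh1a1, Bmpr1a and Cavin2. In edgeR those that fell were Vpreb3, Ebf1 (-4.41, adjusted p = 1.5e-15), Igll1, Cd79a, Car1, Hmga2, Vpreb1, Slc25a21, Pax5 and Ermap. Vpreb3 and Igll1, at 0 in both aged libraries, did not pass with DESeq2.

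Gene lists fixed before the data were examined are described by their median log2 ratio relative to the median of all genes in the same contrast, which was -0.14 for age without EGF, -0.19 for age with EGF, 0.32 for EGF in young mice and 0.23 for EGF in aged mice. HSC ageing genes had a relative median of 2.21 in aged PBS cells, against a central 95% of -0.07 to 0.15 in 10000 random lists matched on expression. At least 1.5-fold higher were 26 of its 33 members, and 29 rose with age in the edgeR model (29 adjusted over the list alone). Nupr1, Plscr2, Wwtr1 and the retinaldehyde dehydrogenase Aldh1a1 (7.05-fold, 6.15 to 8.11) were among them, while Jun, the member with the most UMIs, was 1.09-fold lower. The median was 2.30 within stem-like clusters and 0.53 within the multipotent-like class. Antigen presentation genes were also higher. The 7 genes of MHC class II had a relative median of 2.17, with H2-Eb1 at 12.1-fold (9.83 to 15.1; ENSMUSG00000060586, chromosome 17, 34305867 to 34316674), H2-Aa at 7.08-fold (6.15 to 8.19) and the invariant chain Cd74 at 6.48-fold (5.78 to 7.27). With age, 5 of the 7 rose (7 adjusted over the list alone), and DESeq2 called 4. The class II median was 2.38 within stem-like clusters. Of 13 MHC class I genes 9 rose (10 adjusted over the list alone, median 0.57), among them B2m (1.55-fold, 1.52 to 1.58), H2-T23 (1.86-fold) and H2-Q7 (1.67-fold). Of 23 interferon response genes 8 rose (12 adjusted over the list alone, median 0.60), including the GTPases Iigp1 (3.29-fold) and Igtp (2.51-fold, 2.19 to 2.88) and the membrane protein Ifitm3 (1.82-fold). DESeq2 called 2 of the 23, and it called 26 HSC ageing and 6 MHC class I genes higher.

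Lineage genes moved apart with age. The multipotent and lymphoid priming list had a median of -0.61, which was -0.74 within stem-like clusters and -0.27 within the multipotent-like class. Of its 19 members 14 were at least 1.5-fold lower in aged PBS cells, and 12 fell in edgeR's model (14 adjusted over the list alone). The cytokine receptor Flt3 was 2.21-fold lower (2.08 to 2.34), the chromatin organiser Satb1 2.16-fold (2.00 to 2.33) and the tetraspanin Cd53 2.32-fold (2.12 to 2.55), and the interleukin receptor Il7r stood at 11.6 CPM in young and 2.39 CPM in aged PBS cells. Erythroid genes had a median of -1.16, and 11 of 16 fell (12 adjusted over the list alone) while Cited4 rose. Within stem-like clusters the erythroid median was 0.61, and the share of erythroid-like cells was 8.23% (6.80 to 9.84) in young PBS and 1.65% in aged PBS. Of 20 megakaryocyte and platelet genes tested 9 rose (9 adjusted over the list alone, median 0.40), among them the adhesion molecule Selp (5.63-fold, 4.81 to 6.63) and the caveola protein Cavin2 (5.51-fold, 4.91 to 6.19), both also on the ageing list. The median was -0.33 within the multipotent-like class, and megakaryocyte-like cells made up 7.62% (6.24 to 9.19) of young PBS and 10.2% (8.87 to 11.6) of aged PBS cells. Stem cell identity genes had a median of 0.36, with 8 rising and 3 falling among 31 (12 and 4 adjusted over the list alone). Hoxb5 stood at 3.64 CPM in young and 10.8 CPM in aged PBS cells and rose, Angpt1, the member with the most UMIs, was 1.10-fold lower, and Hlf, Hmga2 and Hoxa9 fell. The median of this list was -0.16 within the multipotent-like class. Granulocyte and monocyte genes went both ways (median -0.12, and 0.22 within the multipotent-like class): Ctsg, Elane, Ms4a3 and Prtn3 rose, Prtn3 by 1.73-fold (1.67 to 1.79) without EGF, while the log2 ratio of Ctsg with EGF turned from 0.74 to -1.18 within stem-like clusters, and Csf3r, Cst7 and Gfi1 fell. With DESeq2, 7 multipotent and lymphoid and 7 erythroid genes were called lower, 6 megakaryocyte genes higher, 8 stem cell identity genes higher and 4 lower, and 3 granulocyte and monocyte genes higher and 1 lower.

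Of 21 genes of the ERK response, the transcriptional output of the pathway below EGFR, 8 rose (10 adjusted over the list alone, median 0.27 without EGF). Ccnd1 was 1.67-fold higher (1.50 to 1.86), and the phosphatase Dusp4 stood at 4.57 CPM in young and 12.1 CPM in aged PBS cells. The median was -0.02 within the multipotent-like class. Of 20 immediate early and handling stress genes 9 rose (13 adjusted over the list alone, median 0.22), with Klf2 at 1.52-fold (1.43 to 1.61) and Fos at 1.06-fold. The median of 0.22 lay inside the range of random lists matched on genomic span as well (0.02 to 0.25), and it was -0.41 within the multipotent-like class. The median of NF-kB and cytokine genes was -0.21, with the chemokine Ccl3 2.60-fold lower (2.30 to 2.94), while Bcl3, Cxcl2, Nfkbia, Tnf and Traf1 rose over both treatments. Among 12 CDK inhibitors and senescence genes Cdkn1a, Cdkn1c, Cdkn2c and Cdkn2d rose and Cdkn1b fell (4 and 1 adjusted over the list alone, median 0.07), Cdkn2c being 2.72-fold higher (2.27 to 3.29) and Cdkn1c 1.83-fold (1.61 to 2.07). Of the non-homologous end joining genes, which repair double-strand breaks, Prkdc, Xrcc5 and Dclre1c fell (log2 fold changes -0.32, -0.36 and -0.39, edgeR adjusted p = 0.046, 0.030 and 0.033, 4 genes adjusted over the list alone, median -0.11). With DESeq2 their adjusted p values were 0.34, 0.33 and 0.41. Among p53 targets Cdkn1a, Perp, Plk2 and Pmaip1 rose (5 adjusted over the list alone, median 0.06). As higher with age, DESeq2 called 4 ERK response, 6 immediate early, 1 NF-kB and cytokine (Nfkbia), 3 CDK inhibitor and senescence and 1 p53 target gene.

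**Figure D1:**
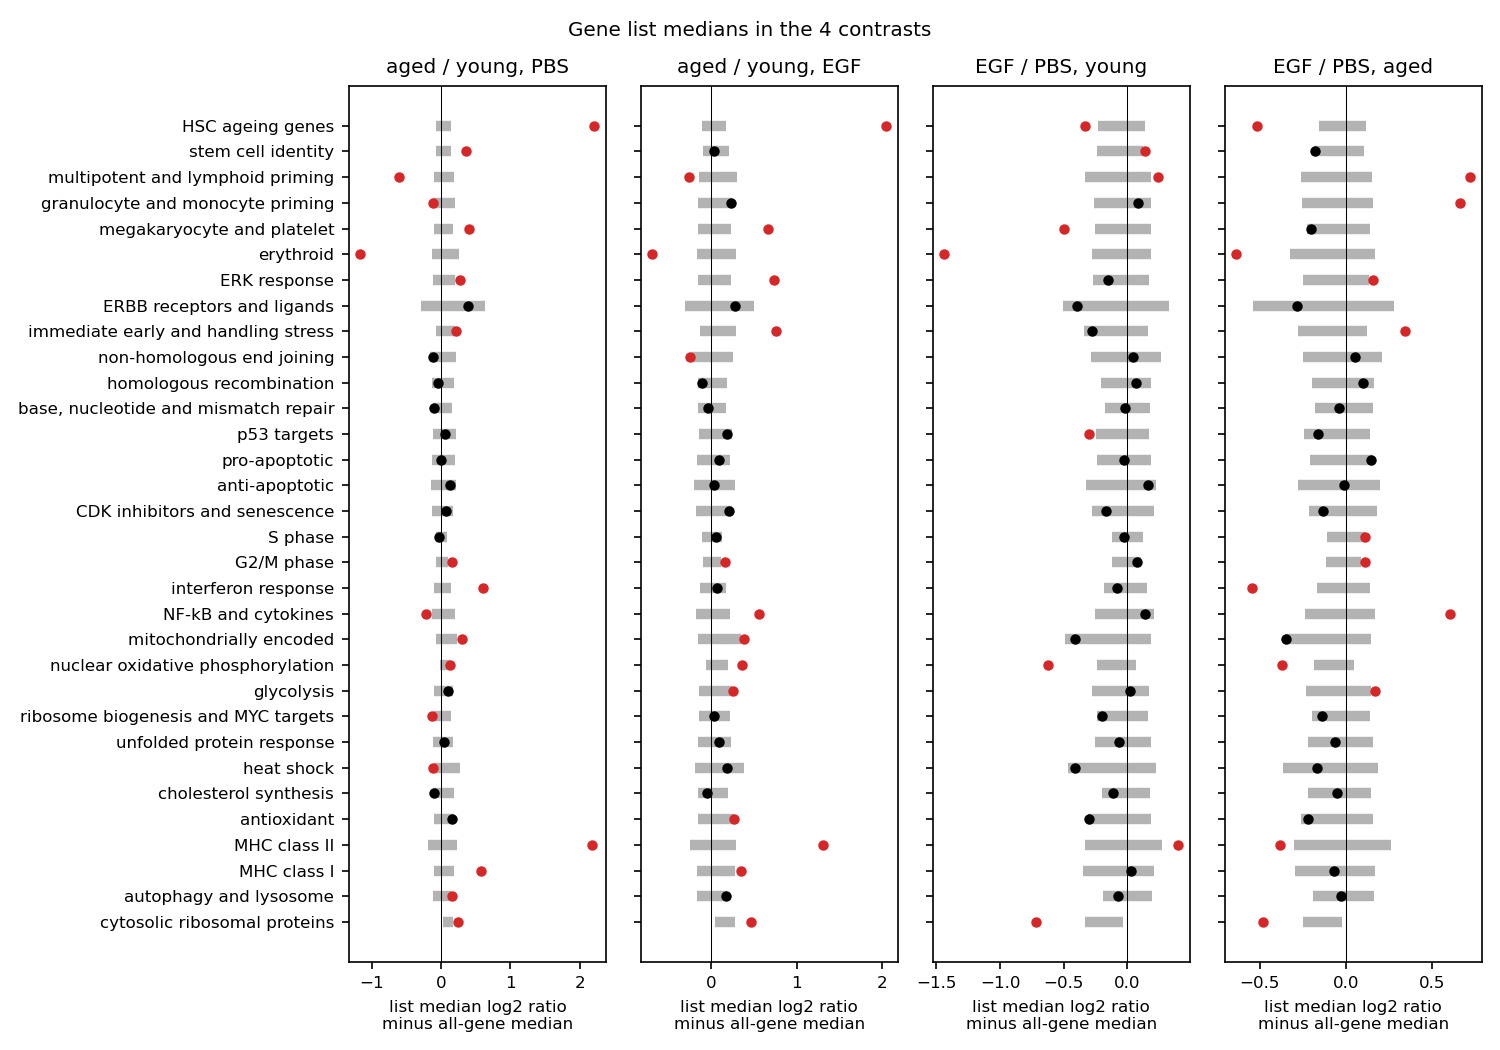
Each panel plots, for 1 contrast between libraries, the median log2 ratio of each fixed gene list minus the median of all genes (points) and the central 95% of 10000 random lists matched on expression (grey bars). Red points lie outside the grey bar. HSC ageing genes stand at 2.21 and 2.06 in the age contrasts and at -0.33 and -0.52 in the EGF contrasts.

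EGF in young mice was compared with PBS in young mice. The genes highest after EGF were the Wnt pathway receptor Ptk7 (2.62-fold, 2.19 to 3.14), the ubiquitin ligase Rnf220 (2.55-fold), Rnf150 (2.53-fold, 2.31 to 2.77), the neuron navigator Nav1, the mannosidase Man1c1 and the kinase Dclk2 (2.41-fold each), Cd74 (2.40-fold, 2.12 to 2.72), Ralgps1, Auts2 (2.31-fold) and the organic anion transporter Slco3a1 (2.31-fold, 2.22 to 2.40). Lowest were Cdk8 (28.9-fold, 27.6 to 30.2), Cmss1 (20.1-fold), Il31ra (10.6-fold, 8.76 to 13.0), Lars2 (9.87-fold), and the histone genes Hist1h4d (9.53-fold), Hist2h2bb, Hist1h4h (8.24-fold, 7.38 to 9.22), Hist1h3e and Hist1h2ak. Cdk8, Cmss1, Il31ra and Lars2 were lower alongside ribosomal RNA locus genes (below), and an effect of EGF on them was not told apart from that. The metallothionein genes Mt1 and Mt2 were 4.44-fold (4.09 to 4.84) and 5.11-fold (4.36 to 6.02) lower. Erythroid genes had a relative median of -1.44 (-0.30 within stem-like clusters and -0.21 within the multipotent-like class), with Car1 3.26-fold lower (3.11 to 3.41), although haemoglobin Hbb-bs was 6.75-fold higher (5.17 to 8.96). The platelet chemokine Pf4 was 3.54-fold lower (3.30 to 3.79), and megakaryocyte and platelet genes had a median of -0.50 (-0.10 and -0.18 within these classes). The shares of erythroid-like and megakaryocyte-like cells were 2.14% (1.29 to 3.32) and 1.24% (0.620 to 2.21) with EGF, against 8.23% and 7.62% with PBS.

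Multipotent and lymphoid priming genes had a relative median of 0.24 in young mice but a relative mean of -0.11. Flt3 was 2.15-fold higher with EGF (2.06 to 2.24) and Satb1 2.06-fold (1.95 to 2.18), whereas Ly6d, a marker of B-lymphoid commitment, stood at 19.1 CPM with PBS and 1.89 CPM with EGF. Within stem-like clusters the median was 0.25 and the mean 0.30, whereas within the multipotent-like class the median was 0.12, inside the random range (-0.34 to 0.14), and the mean -0.33. HSC ageing genes had a relative median of -0.33, with Mt1 and Mt2 at the low end, and -0.10 within stem-like clusters. The list's unadjusted median log2 ratio was -0.02, and its relative median turned to 0.025 under a gene filter of 500 UMIs and 50 CPM. The RNA-binding protein Msi2, of the stem cell identity list, was 2.03-fold higher (1.99 to 2.07). That list's median was 0.14, inside the range of random lists matched on span as well (-0.14 to 0.18), and -0.13 within stem-like clusters. MHC class II genes had a median of 0.40, but -0.01 within stem-like clusters, -0.19 within the multipotent-like class and -0.13 in G1 cells. Medians of 0.08 for granulocyte and monocyte, 0.14 for NF-kB and cytokine, -0.15 for ERK response and -0.28 for immediate early and handling stress genes lay inside the random range matched on expression. Matched on span as well, the first pair lay above the range (-0.42 to -0.0036 and -0.31 to 0.08). Within stem-like clusters the granulocyte and monocyte median was 0.32, above the random range of -0.30 to 0.22, and within the multipotent-like class it was -0.18. Nuclear oxidative phosphorylation genes had a median of -0.62 and cytosolic ribosomal protein genes one of -0.72. Of 7287 genes compared, 1491 were at least 1.5-fold higher and 110 at least 1.5-fold lower. Genes higher made up 93.1% of these calls with CPM and 45.4% with TMM factors. After centring on the all-gene median, 189 were higher and 498 lower.

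EGF in aged mice was compared with PBS in aged mice. The genes highest after EGF were the chemokine Ccl3 (4.07-fold, 3.63 to 4.57; ENSMUSG00000000982, chromosome 11, 83647844 to 83649355), the activation antigen Cd69 (3.46-fold, 3.19 to 3.76), Arpp21 (3.15-fold, 2.64 to 3.77), Satb1 (3.12-fold, 2.90 to 3.35; ENSMUSG00000023927, chromosome 17, 51736187 to 51833290), Rnf220 (2.95-fold, 2.86 to 3.04), the phospholipid transporter Atp8b4 (2.82-fold), the SLAM family receptor Cd244a (2.77-fold), the pro-apoptotic BH3 protein Bcl2l11 (2.77-fold, 2.46 to 3.12), Gkn3 (2.76-fold) and Cd53 (2.73-fold, 2.49 to 2.99). Lowest were Cdk8 (23.9-fold, 22.7 to 25.2), Cmss1, Hist1h4d (12.8-fold), Lars2 (10.0-fold), Il31ra, Hist1h4h, Hist2h2bb, Hist1h3e, Hist1h1e and Hist1h3c. Here too Cdk8, Cmss1, Lars2 and Il31ra were lower alongside ribosomal RNA locus genes. Multipotent and lymphoid priming genes had a relative median of 0.72. Of 17 measured, 12 were at least 1.5-fold higher, with Flt3 at 2.72-fold (2.58 to 2.88; ENSMUSG00000042817, chromosome 5, 147330741 to 147400489). The median was 0.40 within stem-like clusters and 0.40 within the multipotent-like class. Granulocyte and monocyte genes had a median of 0.66, with the transcription factor Irf8 at 2.57-fold (2.21 to 3.01). It was 0.23 within stem-like clusters, above the random range of -0.40 to 0.22, and 0.01 within the multipotent-like class. NF-kB and cytokine genes had a median of 0.60, and 13 of 15 were at least 1.5-fold higher. Immediate early and handling stress genes had a median of 0.34, with Socs3 at 1.94-fold (1.68 to 2.23), against a median of -0.28 in young mice. With 1 library per group, a difference in handling of a library cannot be told apart from EGF here. The ERK response list shares Fos, Egr1 and Dusp1 with that list. Its median was 0.16 (0.07 within stem-like clusters and 0.05 within the multipotent-like class), with Dusp5 at 2.47-fold (2.22 to 2.76).

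HSC ageing genes had a relative median of -0.52 in aged mice with EGF. Below the all-gene median were 27 of 33 members, 6 were at least 1.5-fold lower, and 3 were at least 1.5-fold higher. Nupr1 was 1.85-fold lower (1.73 to 1.99), from 107 to 57.9 CPM, Aldh1a1 1.30-fold (1.21 to 1.39) and Cavin2 1.29-fold (1.20 to 1.38), while Klf6 was 1.67-fold higher (1.61 to 1.74). In CPM without centring, Kcnb2 (1.04-fold higher, 0.971 to 1.12) and Plscr2 (1.09-fold lower, 0.992 to 1.21) did not differ beyond counting error. Both lay below the all-gene median log2 ratio of this contrast, 0.23, so that reading depends on the scaling. Within stem-like clusters the list median was -0.07, inside the random range of -0.17 to 0.12, and within the multipotent-like class it was -1.01. Interferon response genes had a median of -0.55, with Iigp1 2.49-fold lower (2.30 to 2.69) and Ifi44 1.85-fold (1.65 to 2.06), and the median was -0.58 within stem-like clusters. MHC class II genes had a median of -0.38, with H2-Aa and H2-Eb1 each 1.32-fold lower. Nuclear oxidative phosphorylation and cytosolic ribosomal protein genes had medians of -0.37 and -0.48. Of 6933 genes compared, 798 were at least 1.5-fold higher and 86 at least 1.5-fold lower. Genes higher made up 90.3% of these calls with CPM and 61.2% with TMM factors. Centred on the all-gene median, 197 were higher and 236 lower.

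**Figure D2:**
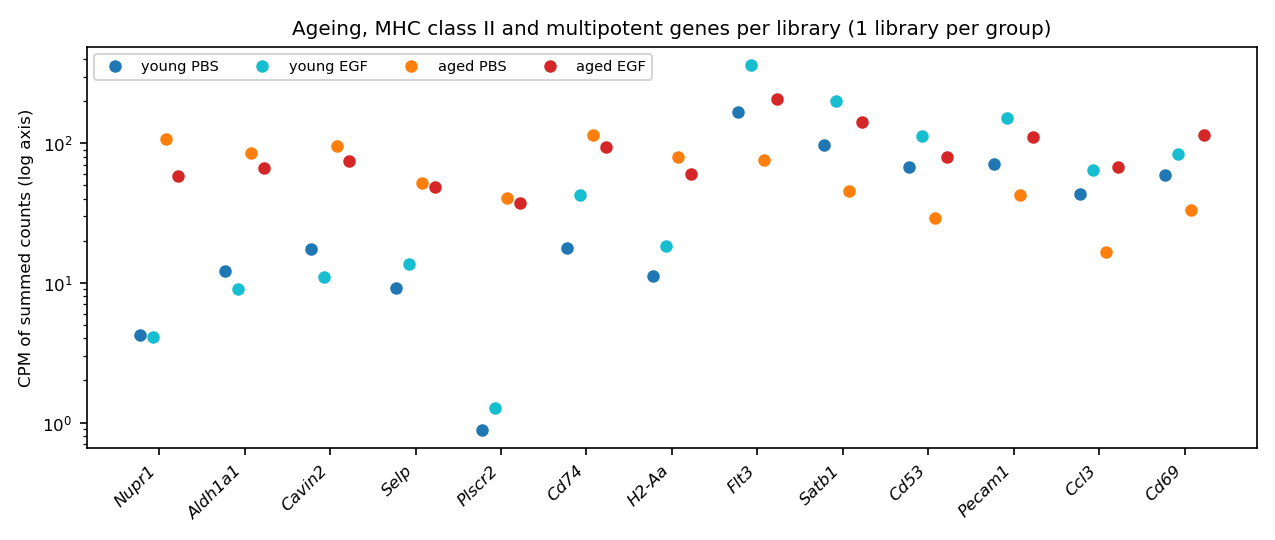
Points give the CPM of summed counts (log axis) of ageing, MHC class II and multipotent genes in each of the 4 libraries, 1 library per group. Nupr1 stands at 4.26 and 4.10 CPM in young mice and at 107 (PBS) and 57.9 CPM (EGF) in aged mice, and Flt3 is higher with EGF at either age.

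Across both ages, the additive edgeR model with age as a term called 1332 genes that rose and 1392 that fell with EGF among 14911 tested. DESeq2, which gave an adjusted p for 9729 genes, called 550 and 556, of which 541 and 515 were also called by edgeR. Of the edgeR calls, 104 that rose and 333 that fell had no adjusted p in DESeq2. Without the age term edgeR called 0 and 29 genes, with 1705 at an unadjusted p under 0.05. Both EGF libraries were deeper per cell than both PBS libraries, and the model cannot tell EGF apart from a library difference that goes with it. The genes of lowest edgeR p that rose were the adhesion molecule Pecam1 (log2 fold change 1.00, adjusted p = 5.5e-07; ENSMUSG00000020717, chromosome 11, 106654217 to 106750628), Satb1 (1.11, adjusted p = 7.1e-07), Tm6sf1, Slco3a1 (1.08), Atp8b4, Flt3 (1.04, adjusted p = 1.3e-06), Rnf220 (1.23), Gm20342, Rnf150 and the interleukin receptor Il1r1 (0.95). Each was higher with EGF at both ages, without correction for genomic span. In edgeR those that fell were Gm15564, AY036118, Hist1h4h, Cdk8 (-4.94, adjusted p = 3.6e-18), Lars2, Hist1h3e, Il31ra, Hist1h4d, Cmss1 and Hist2h2bb. These genes are taken up with the ribosomal RNA locus and histone genes below. At least 1.5-fold higher at both ages were also the Notch coactivator Maml3 (2.26-fold in young and 2.29-fold in aged mice), Parp8, Rbm47 and Fgf13. Of 19 multipotent and lymphoid priming genes 10 rose (11 adjusted over the list alone), among them Flt3, Cd34, Cd48, Satb1 and Dntt, while Ikzf3 and Ly6d fell. DESeq2 called 8 of this list higher and 0 lower. Of 18 granulocyte and monocyte genes 9 rose (9 adjusted over the list alone), including Csf3r (0.72) and Cebpa (0.82), and DESeq2 called 2. Of 16 NF-kB and cytokine genes 7 rose (9 adjusted over the list alone), among them Nfkb1 (0.45), Nfkbiz (0.47), Ccl3 and Tnf, and DESeq2 called 3. Of 33 HSC ageing genes 14 fell (16 adjusted over the list alone, edgeR), among them Nupr1 (-0.87, adjusted p = 0.00012), Aldh1a1 (-0.62), Cavin2 (-0.71), Mt1 and Mt2, and Alcam rose. DESeq2 called 3 of the 14. Of 23 interferon response genes 8 fell (10 adjusted over the list alone), and DESeq2 called 1. In young mice the median of this list was -0.08, inside the random range (-0.18 to 0.15), and 0 members were at least 1.5-fold lower, Iigp1 having log2 ratios of -0.08 in young and -1.31 in aged mice.

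Of 58 nuclear oxidative phosphorylation genes 37 fell (42 adjusted over the list alone), including Cox7b (-0.69) and Uqcr11 (-0.68), and DESeq2 also called 37. Of 81 cytosolic ribosomal protein genes 43 fell (63 adjusted over the list alone), including Rps29 (-0.77). The EGF log2 ratio followed the genomic span of the gene across genes, with a Spearman rho of 0.63 in young and 0.39 in aged mice. The age log2 ratio followed it the opposite way, with a rho of -0.29 without and -0.58 with EGF. Corrected for span, the medians of oxidative phosphorylation genes moved from -0.62 to -0.30 in young and from -0.37 to -0.20 in aged mice, and those of ribosomal protein genes from -0.72 to -0.31 and from -0.48 to -0.24. Against random lists matched on span as well, the uncorrected medians of both lists lay below the central 95% at both ages. Of 16 erythroid genes 9 fell (11 adjusted over the list alone), among them Car1 (-1.75), Car2 (-0.70), Klf1 and Ermap, whereas Hba-a1 and Hbb-bs rose. The log2 ratio of Car1 with EGF in aged mice turned from -1.30 to 1.04 without erythroid-like and pro-B-like cells, and to 1.86 in G1 cells. Erythroid-like cells made up 1.65% of aged PBS and 0.897% (0.388 to 1.76) of aged EGF cells. Of 20 megakaryocyte and platelet genes 7 fell (9 adjusted over the list alone), among them Pf4 and Treml1, and Plek rose. Pf4 was lower in young mice only (log2 ratio -1.82, against 0.14 in aged mice), and the list median in aged mice was -0.20, inside the random range (-0.22 to 0.14). Megakaryocyte-like cells made up 10.2% of aged PBS and 5.49% (4.09 to 7.20) of aged EGF cells. Of 31 stem cell identity genes Hmga2 (0.58), Msi2 (0.70) and Runx1 (0.55) rose and 6 fell (4 and 7 adjusted over the list alone). Those that fell were Cdkn1c, Ctnnal1, Gfi1b, Pdzk1ip1, Tal1 and Txnip. In aged mice the relative median of this list was -0.18, with 21 members below the all-gene median. It lay inside the random range matched on expression (-0.19 to 0.10) but below that matched on span as well (-0.11 to 0.16). Among 21 ERK response genes edgeR called Dusp5 (0.67, adjusted p = 0.0014) and Spred2 higher (2 adjusted over the list alone). Among 20 immediate early and handling stress genes Nr4a1 and Socs3 rose (2 adjusted over the list alone). Among CDK inhibitors and senescence genes Cdkn1c, Cdkn2d and Hmgb1 fell and Glb1 rose. With DESeq2, 70 ribosomal protein genes were called lower, 4 erythroid genes lower and 0 higher, 2 megakaryocyte genes lower and 1 higher, and 4 stem cell identity genes higher and 2 lower. It called 2 ERK response genes and 1 immediate early gene higher, and 1 senescence gene in each direction.

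No gene of the DNA repair lists passed for EGF. The counts were 0 of 11 non-homologous end joining, 0 of 16 homologous recombination and 0 of 18 base, nucleotide and mismatch repair genes in edgeR, 0 in DESeq2, and 2, 4 and 1 genes with an unadjusted p under 0.05, all higher with EGF. Relative medians were 0.04, 0.07 and -0.02 in young and 0.05, 0.10 and -0.04 in aged mice, each inside the random range. The ligation factor Xrcc4 was 1.39-fold higher with EGF in young and 1.12-fold in aged mice without centring. The aged value lay below the all-gene median log2 ratio of 0.23. With age, Parp1 fell among the 18 repair genes, and 0 of 16 homologous recombination genes passed in edgeR or DESeq2, with 2 at an unadjusted p under 0.05. None of the 7 MHC class II genes passed for EGF in edgeR, with 0 at an unadjusted p under 0.05 and 0 in DESeq2.

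The EGF log2 ratios of young and aged mice, which share no library, were correlated across 6760 genes, which are not independent replicates, with Pearson's r = 0.78 and Spearman's rho = 0.71. On the same side of the all-gene median in both were 76.4% of genes. Corrected for genomic span, r was 0.74. At least 1.5-fold higher at both ages were 508 genes, of 1311 in young and 785 in aged mice, where independent lists would share 152, and at least 1.5-fold lower were 45, where independent lists would share 0.872. Relative to the all-gene medians, the EGF ratio was at least 1.5 times larger in aged than in young mice for 91 genes and at least 1.5 times smaller for 62 of 6758. These differences were not tested, since 4 libraries leave no degree of freedom for an interaction. At both ages the EGF library also differed from the PBS library in depth per cell and in the share of ribosomal RNA locus genes. A library difference common to both ages can raise r and these overlaps too, and it cannot be told apart from EGF here. Pf4 (log2 ratio -1.82 in young and 0.14 in aged mice), Mt2 (-2.35 and -0.64), Mt1 (-2.15 and -0.68), Ccl3 (0.55 and 2.02), Cd69 (0.51 and 1.79) and Arpp21 (0.54 and 1.65) were on the larger side. Hist1h3c (-0.97 and -2.57), Cd74 (1.26 and -0.30) and Iigp1 (-0.08 and -1.31) were on the smaller side.

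The age ratio without EGF was set against the EGF ratio in aged mice to ask whether EGF moved genes opposite to age. Across 6760 genes r was -0.39 and rho -0.53. The aged PBS library enters both ratios, and simulated libraries with no effect gave r = -0.46. The covariance was -0.0516 against a simulated -0.00195, while the observed r was weaker than the simulated one. A deviation of the aged PBS library larger than that simulated would also make the covariance more negative. The gap between the covariances therefore does not show that EGF moved genes opposite to age. Of the 227 genes at least 1.5-fold lower with age, 189 also passed the gene filter in the EGF contrast of aged mice. Of these, 133 were at least 1.5-fold higher with EGF, where independent lists would share 19.9. A gene under the filter in aged PBS entered only if it passed in aged EGF, which raises this overlap. Of 198 genes at least 1.5-fold higher with age, 30 were at least 1.5-fold lower with EGF, where independent lists would share 2.58. Part of each excess may also come from the shared library, which could not be split. Flt3, Satb1, Cd53, Rnf220 and Ccl3 were lower with age and higher with EGF, and Nupr1 and Iigp1 were higher with age and lower with EGF.

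Aged EGF cells were then compared with young EGF cells. The ageing transcripts remained far apart: Kcnb2 was 285-fold higher in aged cells (131 to 779), Rorb 31.6-fold (22.1 to 46.7), Wwtr1 31.1-fold, Plscr2 29.1-fold (20.1 to 43.8) and Nupr1 14.1-fold (11.4 to 17.6). HSC ageing genes had a relative median of 2.06 (0.39 within the multipotent-like class), and 27 of 33 were at least 1.5-fold higher. MHC class II genes had a median of 1.31, with H2-Eb1 at 4.31-fold (3.73 to 4.99). Multipotent and lymphoid priming genes had a median of -0.27, and 0.01 within the multipotent-like class, with Flt3 1.74-fold lower (1.68 to 1.81) and Satb1 1.43-fold lower (1.36 to 1.50). Interferon response genes had a median of 0.07, inside the random range, and DNA repair by non-homologous end joining one of -0.25, below the range of lists matched on expression (-0.22 to 0.26) but inside that of lists matched on span as well (-0.29 to 0.15). Medians were 0.73 for the ERK response, 0.76 for immediate early and handling stress genes, 0.56 for NF-kB and cytokine genes, 0.67 for megakaryocyte and -0.69 for erythroid genes. Corrected for genomic span, they were 0.45, 0.45, 0.35, 0.36 and -0.84, and the multipotent and lymphoid median was -0.12. The megakaryocyte median was -0.07 within the multipotent-like class, and the erythroid median was 0.58 within stem-like clusters. Klf2 was 2.42-fold higher (2.30 to 2.54), Socs3 2.79-fold (2.38 to 3.27) and Cdkn1a 2.17-fold (1.92 to 2.47). Of 7341 genes, 138 were at least 1.5-fold higher and 478 lower. Genes higher made up 22.4% of these calls with CPM and 51.4% with TMM factors. With centring on the all-gene median, 246 were higher and 124 lower. The age ratios with and without EGF had r = 0.75 and rho = 0.61 across genes, and shared 93 genes at least 1.5-fold higher and 100 at least 1.5-fold lower, where independent lists would share 3.39 and 11.8.

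Cell classes were read from clusters of all 4 libraries. Stem-like clusters held 29.4% (26.9 to 31.9) of young PBS, 33.4% (30.3 to 36.7) of young EGF, 51.9% (49.6 to 54.1) of aged PBS and 40.4% (37.1 to 43.7) of aged EGF cells. Multipotent-like clusters held 46.0%, 49.4%, 23.6% and 36.1%. Different clusters made up the stem-like class in each group: clusters 6 and 5 in young PBS, cluster 5 in young EGF, clusters 1 and 4 in aged PBS and cluster 4 in aged EGF. Within the multipotent-like class, clusters 2 and 0 held 295 and 207 cells in young PBS, 8 and 325 in young EGF, 315 and 86 in aged PBS, and 43 and 195 in aged EGF. The CD34- KSL gate and the depth gap between PBS and EGF libraries can set these shares. Clustering was run without correction for library, so clusters can also split by library. Cluster 1 had 3 stem markers among its 50 leading genes, and held 0 young EGF and 50 aged EGF cells. Clusters 4, 5 and 6 had 1 each, and were named from 14, 10 and 10 raised of 16 stem markers. Values within stem-like clusters therefore compare partly different clusters. Cycling cells made up 8.76%, 13.7%, 12.7% and 17.2%. In cells thinned to 6000 UMIs, the share called S phase was 32.4% (29.8 to 35.1), 34.0% (30.8 to 37.3), 26.1% (24.1 to 28.2) and 30.6% (27.6 to 33.7), and the share called G2/M 10.4%, 11.0%, 11.2% and 12.1%, in the order young PBS, young EGF, aged PBS and aged EGF. Unthinned shares of S phase were 31.5%, 33.2%, 26.1% and 30.9%. Thinning left out 86, 35, 144 and 0 shallower cells, and free RNA can enter such calls. The relative medians of the S phase list were -0.04 and 0.05 for age without and with EGF, and -0.03 and 0.11 for EGF in young and aged mice, and within stem-like clusters they were -0.12, -0.52, 0.39 and 0.15. Those of the G2/M list were 0.16, 0.16, 0.08 and 0.11, and within stem-like clusters they were -0.02, -0.17, -0.06 and -0.22. Mki67, a marker of cycling cells, stood at 117, 162, 109 and 102 CPM.

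Transcripts from a ribosomal RNA locus were lower in the EGF libraries at both ages. Gm42418 (chromosome 17, 39846958 to 39848788, plus strand) and AY036118 (39847113 to 39848035, minus strand) overlap each other and the annotated ribosomal RNA gene CT010467.1 (39846353 to 39848827). Together they took 3.61% of UMIs in young PBS and 2.94% in aged PBS, against 0.0867% in young EGF and 0.0825% in aged EGF. Gm42418 was 42.4-fold lower with EGF in young mice (41.8 to 43.1) and 36.2-fold in aged mice (35.6 to 36.8). Replication-dependent histone genes, a list set after the data were seen, had relative medians of -1.36 and -1.44 with EGF, and 47 of 61 fell in edgeR's model (26 with DESeq2). Also lower with EGF at both ages were Cdk8, Cmss1, Lars2, Camk1d, Il31ra and Gm15564. As a group they took 0.811% of UMIs in young PBS and 0.623% in aged PBS, against 0.0556% in young EGF and 0.0435% in aged EGF. Whether they were lowered by EGF or along with the locus genes, for which library preparation is a candidate explanation, was not tested. With histone genes, ribosomal RNA locus genes and this further group left out, the correlation of EGF ratios between ages was r = 0.71.

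**Figure D3:**
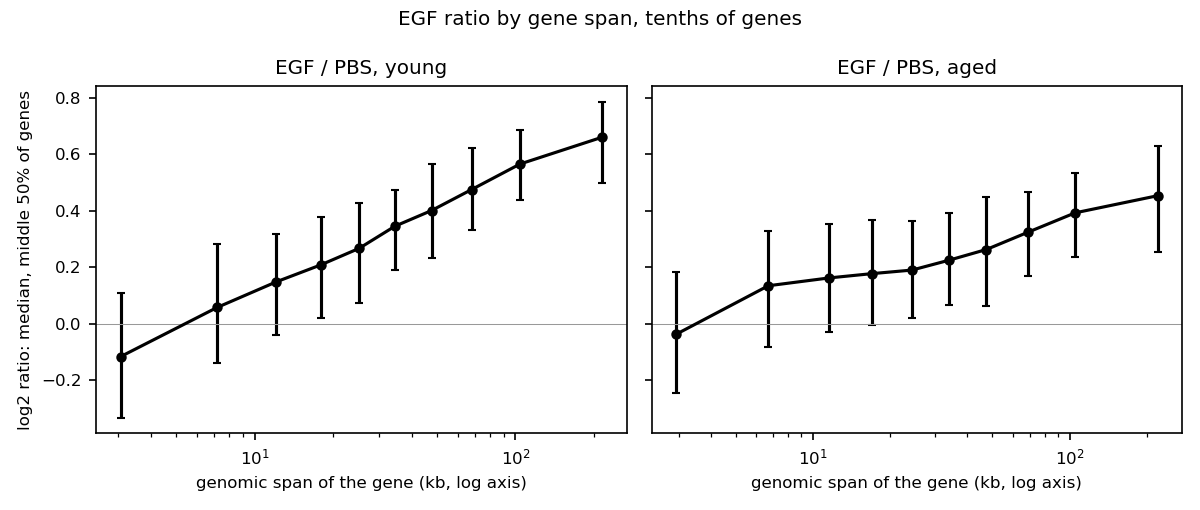
Genes were split into 10 equal groups by genomic span (kb, log axis), and points give the median log2 ratio of EGF over PBS, with bars for the middle 50% of genes, in young (left) and aged mice (right). The ratio is higher for longer genes, with a Spearman rho of 0.63 in young and 0.39 in aged mice.

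For the remaining lists, relative medians with EGF in young and aged mice were 0.02 and 0.17 for glycolysis (Gpi1, Pfkl, Pgam1 and Pkm rose), -0.20 and -0.14 for ribosome biogenesis and MYC targets (5 fell, among them Ncl and Eif4ebp1), and -0.41 and -0.35 for mitochondrially encoded genes (5 fell, among them mt-Atp8 and mt-Nd6). They were -0.30 and -0.22 for antioxidant genes (Gclm, Sod1, Sod2, Txn1 and Txnrd1 fell), -0.41 and -0.17 for heat shock genes (Hspe1 and Hsph1 fell), and -0.07 and -0.06 for the unfolded protein response (Asns, Ddit3 and Dnajb9 fell, although the log2 ratio of Asns in young mice turned from -1.03 to 0.33 within stem-like clusters). They were -0.11 and -0.05 for cholesterol synthesis (Stard4 fell), -0.07 and -0.03 for autophagy and lysosome genes (Atg7 rose, Atg12 and Gabarapl1 fell), -0.30 and -0.16 for p53 targets (Bax and Rrm2b fell), -0.03 and 0.14 for pro-apoptotic genes (Bcl2l11 among those that rose, Bax among those that fell), and 0.16 and -0.01 for anti-apoptotic genes (Bcl2 and Birc3 rose). MHC class I genes had medians of 0.03 and -0.07 (Tap2 rose, H2-Q7 fell), ERBB receptors and ligands -0.40 and -0.28, and CDK inhibitors and senescence genes -0.17 and -0.14. Of these medians, those of p53 targets in young mice and of glycolysis in aged mice lay outside the random range matched on expression. With span matched as well, p53 targets in young mice lay inside the range, whereas glycolysis and pro-apoptotic genes in aged mice and MHC class I genes in young mice lay above it. With DESeq2, 3 glycolysis genes and 1 anti-apoptotic gene were called higher, and 6 ribosome biogenesis, 7 mitochondrially encoded, 3 antioxidant, 1 heat shock, 2 unfolded protein response and 1 autophagy gene lower. It called 0 genes of cholesterol synthesis and 0 p53 targets, and 1 gene in each direction of the pro-apoptotic and the MHC class I list.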

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

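The tests of depth and of intronic RNA for the gene span trend were set before their result was seen, and the other tests were chosen only after it. The relative list median of MHC class II genes with EGF was 0.40 in young and -0.38 in aged mice over all kept cells, a difference of -0.78 that was not tested, and 0 of the 7 genes passed for EGF in edgeR (0 at an unadjusted p under 0.05, 0 in DESeq2). The young median was not positive within stem-like clusters (-0.01), within the multipotent-like class (-0.19) or in G1 cells (-0.13), where the aged medians were -0.46, -0.68 and -0.42. Outside the cells compared, 65 plasma-like and 40 T or NK-like cells were present, and how they came through the gate was not tested.

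Ribosomal RNA locus genes and replication-dependent histones were lower in both EGF libraries. Fewer cells in S phase would lower the S phase list too, though not necessarily by a like amount. Its lower relative median was -0.026, against -1.36 and -1.44 for histones. The share of cells called S phase, scored with the same list, was 32.4% in young PBS and 34.0% in young EGF. It was 26.1% in aged PBS and 30.6% in aged EGF. Neither share was lower with EGF, which argues against fewer cells in S phase. A library preparation that differed between EGF and PBS libraries is a candidate explanation, since in plasma-like and T or NK-like cells the log2 ratio of the summed locus genes was -4.46 in aged and -4.52 in young mice, against -5.15 and -5.38 in the kept cells. Summed histones were less strongly lowered in those cells (-0.65 in aged and -0.48 in young mice) than in the kept cells (-1.41 and -1.19). An effect of EGF on all cell types alike and free RNA in droplets stay open, as the labels give no batch.

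EGF log2 ratios trended with the genomic span of the gene. More UMIs per cell in the EGF libraries may raise long genes, but in cells of 10000 to 20000 UMIs the Spearman rho was 0.577 in young and 0.382 in aged mice, against 0.631 and 0.387 in all kept cells. The median cell of that window still held 13076 UMIs in young PBS and 13152 in aged PBS, against 15094 in young EGF and 15424 in aged EGF. Depth was thus brought closer but not made equal, and a part from depth stays open. In genes with hardly any intron, rho with exon length was 0.398 in young and 0.280 in aged mice. Histone and ribosomal RNA locus genes, lower with EGF, were not taken out of that set. These values therefore cannot decide whether intronic RNA is the whole cause. At equal exon length the ratio still trended with intron length (0.432 and 0.232), so intronic RNA stays open. Biological length dependence was not tested and stays open.

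Multipotent and lymphoid priming genes were higher in the EGF libraries. More multipotent-like cells as the whole cause in aged mice are argued against by a median of 0.40 within stem-like clusters and 0.40 within the multipotent-like class. Most markers that name the multipotent-like class, among them Flt3, Cd34, Cd48, Satb1 and Dntt, are also on this list, so the classes are not independent of it. Within either class the aged PBS and aged EGF cells lay mostly in different clusters, so a shift of cells between clusters of a class stays open. The span trend is argued against by percentiles of 99.9 in young and 100 in aged mice among random lists matched on expression and span. An aged PBS library out of line could not be excluded: without that library, the young median was 0.24, and 0.196 without erythroid-like and pro-B-like cells, but the means were -0.11 and -0.51. Within stem-like clusters of young mice the median was 0.25 and the mean 0.30, which goes against this explanation. Within the multipotent-like class the young median was 0.12, inside the random range, and the mean -0.33, which goes with it. An effect of EGF itself stays open, untested beyond 1 library per group.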

How the results depend on the processing

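The alternatives were chosen before the data were examined, except those marked as added, which were chosen after seeing the data. Multipotent and lymphoid priming genes kept a positive median in both EGF contrasts under all 17 alternatives computed for them, with a range of 0.12 to 0.30 in young and 0.40 to 0.84 in aged mice, and a negative median for age without EGF (-1.06 to -0.27). HSC ageing genes kept a positive median in both age contrasts (0.53 to 2.68 without EGF, 0.39 to 2.495 with EGF) and a negative one with EGF in aged mice (-1.01 to -0.073), whereas with EGF in young mice it was 0.025 under the stricter gene filter. The correlation of the EGF ratios between ages ranged from 0.51 to 0.84, that of the age ratios from 0.69 to 0.84, and that of age without EGF with EGF in aged mice from -0.49 to -0.36. For each change below the cause was not tested, except that a stricter or looser gene filter or ratio leaves fewer or more genes by construction.

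Scaling without mitochondrially encoded and ribosomal protein genes gave 343 (age without EGF), 252 (age with EGF), 684 (EGF in young) and 480 (EGF in aged) higher genes, 237 (age with EGF), 256 (EGF in young) and 175 (EGF in aged) lower genes and 105 smaller EGF ratios in aged than in young mice. TMM scaling gave 293 (EGF in young) and 275 (EGF in aged) higher genes and 187 (age with EGF), 353 (EGF in young) and 174 (EGF in aged) lower genes. Median-of-ratios scaling gave 210 (age with EGF), 274 (EGF in young) and 261 (EGF in aged) higher genes and 163 (age with EGF), 369 (EGF in young) and 186 (EGF in aged) lower genes. Correction for gene span (added) gave 107 (EGF in young) and 178 (EGF in aged) higher genes and 116 (age without EGF), 84 (age with EGF), 186 (EGF in young) and 166 (EGF in aged) lower genes. The mean of each cell's CPM moved the list medians of HSC ageing genes to 2.04 (age without EGF) and -0.13 (EGF in young), of multipotent and lymphoid priming to -0.77 (age without EGF).

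Thinning cells to the same depth gave 776 (age with EGF) lower genes, 868 higher (EGF), 724 higher (age) and 555 lower (age) genes in the additive model and 164 larger EGF ratios in aged than in young mice. It moved the list medians of HSC ageing genes to -0.36 (EGF in aged), of multipotent and lymphoid priming to -0.80 (age without EGF). Use of every barcode in the files gave 873 higher (EGF), 923 lower (EGF) and 615 lower (age) genes in the additive model. It moved the list medians of multipotent and lymphoid priming to 0.49 (EGF in aged). The stricter cell filter moved the list medians of HSC ageing genes to 1.86 (age with EGF). Restriction to G1 cells gave 640 (age without EGF), 770 (age with EGF) and 66 (EGF in young) lower genes and 163 larger EGF ratios in aged than in young mice. It moved the list medians of HSC ageing genes to 2.68 (age without EGF), 2.495 (age with EGF), -0.13 (EGF in young) and -0.29 (EGF in aged), of multipotent and lymphoid priming to -1.06 (age without EGF). It turned the list medians of G2/M phase to -0.13 (age without EGF), -0.093 (age with EGF) and -0.082 (EGF in aged), of MHC class II to -0.13 (EGF in young), of erythroid to 0.39 (age with EGF), of heat shock to 0.11 (age without EGF), of ribosome biogenesis and MYC targets to 0.093 (age without EGF). It turned the log2 ratio of Asns to 0.59 (age without EGF) and Car1 to 1.86 (EGF in aged). Restriction to stem-like clusters gave 250 (age with EGF) higher genes, 907 (age without EGF), 1098 (age with EGF), 62 (EGF in young) and 53 (EGF in aged) lower genes and 140 larger EGF ratios in aged than in young mice. It moved the list medians of HSC ageing genes to 2.30 (age with EGF), -0.098 (EGF in young) and -0.073 (EGF in aged), of multipotent and lymphoid priming to 0.40 (EGF in aged). It turned the list medians of G2/M phase to -0.024 (age without EGF), -0.17 (age with EGF) and -0.22 (EGF in aged), of MHC class II to -0.0057 (EGF in young), of erythroid to 0.61 (age without EGF) and 0.58 (age with EGF), of heat shock to 0.14 (age without EGF), of ribosome biogenesis and MYC targets to 0.085 (age without EGF), of stem cell identity to -0.13 (EGF in young). It turned the log2 ratio of Asns to 0.33 (EGF in young), Asns to 0.61 (age without EGF), Ctsg to -1.18 (age with EGF) and Slc25a21 to 1.29 (age without EGF). Restriction to the multipotent-like class (added) moved the list medians of HSC ageing genes to 0.53 (age without EGF), 0.39 (age with EGF) and -1.01 (EGF in aged), of multipotent and lymphoid priming to -0.27 (age without EGF) and 0.40 (EGF in aged). It turned the list medians of ERK response to -0.024 (age without EGF), of G2/M phase to -0.22 (EGF in aged), of MHC class II to -0.19 (EGF in young), of S phase to -0.043 (EGF in aged), of erythroid to 0.027 (age with EGF), of granulocyte and monocyte priming to 0.22 (age without EGF), of immediate early and handling stress to -0.41 (age without EGF), of megakaryocyte and platelet to -0.33 (age without EGF) and -0.069 (age with EGF), of multipotent and lymphoid priming to 0.0082 (age with EGF), of ribosome biogenesis and MYC targets to 0.12 (age without EGF), of stem cell identity to -0.16 (age without EGF) and -0.075 (EGF in young). Leaving out erythroid-like and pro-B-like cells (added) gave 70 (EGF in young) lower genes and 41 smaller EGF ratios in aged than in young mice. It moved the list medians of HSC ageing genes to 2.38 (age without EGF). It turned the list medians of erythroid to 0.32 (age with EGF), of ribosome biogenesis and MYC targets to 0.057 (age without EGF), of stem cell identity to -0.045 (EGF in young). It turned the log2 ratio of Asns to 0.36 (age without EGF), Car1 to 1.04 (EGF in aged) and Slc25a21 to 1.12 (age without EGF).

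A gene filter of 20 UMIs gave 1275 (age without EGF), 925 (age with EGF), 2912 (EGF in young) and 1845 (EGF in aged) higher genes, 1063 (age without EGF), 1424 (age with EGF), 676 (EGF in young) and 717 (EGF in aged) lower genes, 885 larger and 721 smaller EGF ratios in aged than in young mice and r = 0.51 between the EGF ratios. A gene filter of 500 UMIs and 50 CPM gave 86 (age without EGF), 61 (age with EGF), 889 (EGF in young) and 449 (EGF in aged) higher genes, 104 (age without EGF), 240 (age with EGF), 63 (EGF in young) and 46 (EGF in aged) lower genes and 50 larger and 11 smaller EGF ratios in aged than in young mice. It moved the list medians of HSC ageing genes to 1.51 (age without EGF) and 0.80 (age with EGF). It turned the list medians of HSC ageing genes to 0.025 (EGF in young). A ratio of at least 2 gave 95 (age without EGF), 62 (age with EGF), 78 (EGF in young) and 72 (EGF in aged) higher genes, 42 (age without EGF), 40 (age with EGF), 48 (EGF in young) and 38 (EGF in aged) lower genes and 16 larger and 9 smaller EGF ratios in aged than in young mice. DESeq2 gave 550 higher (EGF), 431 higher (age), 556 lower (EGF) and 255 lower (age) genes in the additive model. The edgeR model with no term for the other factor, where 1705 genes had an unadjusted p under 0.05 for EGF, gave 0 higher (EGF), 152 higher (age), 29 lower (EGF) and 27 lower (age) genes in the additive model. Thinning to 7000 UMIs, the largest multiple of 1000 that at least 75% of the kept cells of every library reach, gave 28.4% of aged PBS cells in S phase.

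Among log2 ratios of single named genes, 3354 values under the alternatives set beforehand moved by less than their counting interval, 2126 moved by more, and 6 changed sign. Under added alternatives these counts were 1525, 605 and 3. A sign change was counted only for a main ratio of at least 1.5-fold that passed the gene filter, with an interval that excluded no change. Sign changes of all other ratios are held in the counts of values that moved by less or by more. In the additive model, 224 fold changes of named genes stayed past the threshold under the alternatives set beforehand, 16 no longer passed and none changed sign. Without a term for age, Atp8b4, Flt3, Gm20342, Il1r1, Pecam1, Rnf150, Rnf220, Satb1, Slco3a1 and Tm6sf1 no longer passed for EGF, and without a term for EGF, Car1, Ermap, Slc25a21 and Vpreb1 no longer passed for age. Leaving out a library was not run as a test, since 3 libraries leave no residual degree of freedom for the 3 coefficients. No paired analysis was possible because each group holds 1 library and the libraries carry no replicate numbers. Depth limits the scarce genes: a count of 0 allows up to 0.156 CPM in young PBS, 0.132 in young EGF, and 0.130 in aged PBS cells.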

Other observations

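Genes that separated the ages did not all move alike with EGF. Kcnb2, a potassium channel subunit, stood at 0.312 and 0.264 CPM in young and at 72.4 and 75.4 CPM in aged cells with PBS and EGF. Nupr1, a stress-responsive regulator, stood at 107 CPM with PBS and 57.9 CPM with EGF in aged cells. Pro-B-like cells, found in a clustering on 30 principal components, numbered 21 in young PBS, 6 in young EGF, 0 in aged PBS and 0 in aged EGF libraries.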
